A study of Rattus norvegicus and Mus musculus with 22 samples.

How the data were processed

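Total RNA was extracted with Trizol, cleaned on RNeasy columns and made into libraries with a directional (strand-preserving) NEBNext kit, per the labels' protocols. The 22 libraries fell into 16 groups in 6 tables. Wild-type mouse islets, mouse hepatocytes and rat INS-1 insulinoma cells each had 2 control and 2 forskolin libraries. The other 10 groups had 1 library each: control and forskolin CRTC2 knockout islets, an INS-1 experiment with control, forskolin, JQ1 with forskolin and A-485 with forskolin, and control and forskolin AR42J cells carrying GFP or NeuroD1. Forskolin was given at 10 µM for 2 h, JQ1 at 1 µM for 4 h and A-485 at 10 µM for 4 h, per the labels. Groups and replicate numbers came from the sample titles. Nothing in the labels says that replicates came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

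For the 3 replicated tables the authors counted reads over RefSeq exons with HOMER on the mm10 or rn6 genome, kept 1 transcript per gene and then ran HOMER's differential expression step, per the file headers. The deposited values are regularised log2 expression, a scale that shrinks differences of low genes towards 0; the log2 unit was read from the values. The same tables hold the authors' log2 fold change, p-value and adjusted p-value for forskolin against control, per the file headers, and the submitters' processing notes name DESeq2 for such comparisons. The same notes name TopHat2 2.0.9 and STAR, and which aligner made which table is not given in the sources used here. The 3 unreplicated tables name no unit; their deposited values behave as FPKM, because low values multiplied by transcript length pile up at 1 constant per library. Ratios between deposited FPKM columns were computed here.

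The replicated comparisons had been planned for read counts. Since the deposited columns are log2 values, limma 3.58.1 in R 4.3.3 was used on them without further transformation, with a variance trend on the mean and Benjamini-Hochberg adjustment. Genes needed a group mean of at least 1 on the log2 scale, and calls were made at adjusted p under 0.05. Fold changes on the regularised scale are smaller than the authors': the slope of the authors' log2 fold change on the column difference was 1.45 in islets and 1.61 in INS-1 cells. Genes called induced also had a log2 fold change of at least 1. Overlaps of induced genes were compared with independent lists by a one-sided Fisher exact test, matching rat and mouse symbols. The planned test of islet against hepatocyte responses needed counts in 1 table, so effects in different tables, which were normalised separately, were only set side by side.

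There were 23 gene lists, written before the data were examined. In the replicated tables they were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation; lists with fewer than 5 tested members were left out. In the unreplicated tables a log2 ratio used a pseudocount of 1 FPKM, which understates changes of low genes, and genes needed 1 FPKM in the highest library. A list's median was placed among 10000 random lists of the same size matched over 20 expression bins, and its interval came from 2000 bootstrap draws of genes, so it covers differences between genes only. Named genes were chosen by a rule fixed before the data were examined. For replicated tables it took the 12 largest increases and 8 largest decreases among called genes with at least 5 CPM and the same direction in both replicate numbers, up to 4 called members per list, and 10 genes that are always named. For unreplicated tables it took the 8 largest ratios each way among genes with at least 10 FPKM, list members and the same always-named genes. A few genes that the rule names are not reported here. No hepatocyte gene passed as the columns are named, so hepatocyte genes were chosen by the same sizes from the authors' deposited table. CPM was obtained by raising 2 to the deposited value and rescaling each library, so it is approximate.

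The steps were tested on simulated data with 200 changed genes per comparison, 50 at each size. At a log2 change of 1, 24 of 50 genes were recovered in the islet design, 50 of 50 in hepatocytes and 49 of 50 in INS-1 cells. At a log2 change of 2 all 50 were recovered in each of the 3 designs. False calls numbered 18 of 13644 genes in islets, 17 of 12592 in hepatocytes and 6 of 10341 in INS-1 cells. They stood beside 24, 50, 33 and 50 genes recovered at changes of 1, 2, -1 and -2 in islets. In hepatocytes all 50 were recovered at each size, and in INS-1 cells 49, 50, 50 and 50. Among all calls the false share thus lay above 0.05 in islets and hepatocytes and below it in INS-1 cells. Camera with the preset correlation called a planted list in each design and 0 of 20 unchanged lists. With an estimated correlation the planted list had an adjusted p of 0.191 in islets, 0.05 in hepatocytes and 0.106 in INS-1 cells, so that setting missed a change known to be present. The simulated genes varied independently of each other. How often the preset correlation calls unchanged lists of genes that vary together was therefore not tested. In the FPKM tables a planted list of 30 genes was placed at percentile 100 in each. In the knockout, inhibitor and AR42J designs 2, 2 and 4 of 40 unchanged lists lay outside the middle 95% of random lists.

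Alternatives included other filters, quantile normalisation, no variance trend, a replicate block, leaving out each library, the authors' deposited comparison, other pseudocounts and TMM scaling of FPKM. TMM scaling moved the median log2 ratio of all genes by less than 0.1 in every contrast. Gene names that a spreadsheet had turned into dates were left out, 25 in the AR42J table, 25 in the inhibitor table and 27 in the knockout table. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.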

Results

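RNA-seq was used to follow the transcriptional response to forskolin, a diterpene that activates adenylyl cyclase and raises intracellular cAMP, in pancreatic and liver cells. Primary cultured islets and hepatocytes came from mice of a black6 strain. INS-1 is a rat insulinoma line that makes insulin, and AR42J is a rat pancreatic tumour line with exocrine features. The series concerns CREB, the transcription factor that cAMP-dependent protein kinase phosphorylates, and how transient and sustained cAMP responses differ between cell types. Depth was low to moderate. The islet libraries held 3.07 and 3.07 M reads in controls 1 and 2 and 3.30 and 3.88 M in forskolin 1 and 2. Hepatocyte libraries held 2.32 and 1.95 M in control 1 and forskolin 1, and 6.13 and 6.20 M in control 2 and forskolin 2. INS-1 totals were 5.33 M in forskolin 1, 4.27 M in control 2 and 2.08 M in forskolin 2, and the total of control 1 is not given in the sources used here. In the unreplicated tables the depth was estimated from the value of 1 read. It came to 2.53 to 3.48 M reads in AR42J cells, 3.86 to 5.51 M in the inhibitor experiment, and 2.12, 5.67, 2.28 and 0.60 M in wild-type control, knockout control, wild-type forskolin and knockout forskolin islets.

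The islet comparison asked which transcripts change within 2 h of forskolin. Immediate-early transcription factors and known CREB targets rose most. Fosl2, an AP-1 subunit, rose by 3.85 on the log2 scale (SE 0.284, adjusted p = 0.00222), a 14.4-fold change. The orphan nuclear receptor Nr4a3 rose by 3.79 (SE 0.269, adjusted p = 0.00199), and Gem, a small GTPase that restrains calcium channels, by 3.83 (SE 0.196, adjusted p = 0.001). Nr4a1 (mm10 chromosome 15, 101266846 to 101274794, plus strand) went from 5.67 ± 0.20 to 8.71 ± 0.47 (log2 expression, SD, n = 2). Crem, which encodes the feedback repressor ICER among its products, lies on mm10 chromosome 18 from 3266354 to 3281747 and rose by 3.60 (SE 0.226, adjusted p = 0.00191). Of 13656 genes tested, 235 rose and 33 fell. With a replicate block 667 rose and 120 fell, with a crossed block 542 and 163, and without a variance trend 159 and 12. Calls in the authors' deposited table numbered 483 and 63.

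Among the 27 tested members of the list of cAMP and CREB targets, 15 rose and none fell, and 22 rose when adjusted over the list alone. Their median log2 change was 2.00, and the list stood above other genes (camera adjusted p = 1.39e-27, but adjusted p = 0.402 with an estimated correlation). Members with large increases were Fos (3.60), the salt-inducible kinase Sik1 (3.33), the MAP kinase phosphatase Dusp1 (3.22), Nr4a2 (3.06), Rgs2 (3.03) and Irs2 (2.97), the insulin receptor substrate that links cAMP to beta cell survival. Per1 stood at a log2 change of 1.73 with an adjusted p of 0.0509, and Pck1 at 1.20 with an adjusted p of 0.486, so neither passed. Both passed with a replicate block and without forskolin 2. Per1 also passed without forskolin 1, with a crossed block, at a group mean of 5, under quantile normalisation and in the authors' deposited table (adjusted p = 8.85e-07), while Pck1 stood at -0.10 without forskolin 1. Of 26 immediate-early genes 18 rose, 18 also when adjusted over the list alone, with a median of 1.87 (camera adjusted p = 2.16e-21; adjusted p = 0.404 with an estimated correlation). They included Klf4 (3.04), Junb (2.87), Maff (2.81), Fosb (2.61), Egr1 (1.99) and Jun (1.71). In islets Junb, Maff, Fosb, Egr1 and Jun lie outside the naming rule, and their calls were not followed through the other settings. Further large increases were in Star, the carrier of cholesterol into mitochondria, by 3.71, in Diras2 by 3.44, and in Cbarp, a calcium channel regulator, by 3.22.

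Of 14 cholesterol synthesis genes 4 rose in islets, 7 when adjusted over the list alone: Cyp51 (1.80), Insig1 (1.45) and Idi1 (1.27) were among those that passed over all genes, and the list's median was 0.94 (camera adjusted p = 6.59e-05; adjusted p = 0.573 with an estimated correlation). Of 15 gluconeogenesis genes 5 rose, 6 when adjusted over the list alone, among them the coactivator Ppargc1a (2.00), the mitochondrial carrier Slc25a25 (2.12), Fbp1 (1.62) and Cebpb (1.29), with a list median of 0.59 (camera adjusted p = 4e-04; adjusted p = 0.402 with an estimated correlation). Hepatocyte markers were unevenly higher in the same libraries: no member of 19 passed, over all genes or over the list alone, although the list's median was 1.46 (camera adjusted p = 7.42e-04; adjusted p = 0.67 with an estimated correlation). Their median difference was 2.74 between forskolin 1 and control 1, with 18 of 19 above 0, and 0.03 between forskolin 2 and control 2, with 10 of 19 above 0. Gluconeogenesis genes had medians of 0.89 and 0.33 in those pairs, cholesterol synthesis genes 0.73 and 0.95, and cAMP and CREB targets 1.89 and 2.25. Without forskolin 1 the hepatocyte marker list turned to a median of -0.31, and 808 genes rose and 131 fell.

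None of 13 integrated stress response and unfolded protein response genes passed over all genes in islets, but 7 rose when adjusted over the list alone, with a median of 0.69 (camera adjusted p = 6.59e-05; adjusted p = 0.402 with an estimated correlation). The chaperone partner Bag3 (1.84) was the 1 member of 10 heat shock genes that rose, also over the list alone, and that list's median was 0.40 (camera adjusted p = 0.00816; adjusted p = 0.404 with an estimated correlation). Of 33 components of the cAMP pathway 4 rose, 7 up and 1 down when adjusted over the list alone. The 4 were Crem, Sik1, Rgs2 and Sik2 (1.42), while the list's median was 0.09 (camera adjusted p = 0.0266, 0.0745 under quantile normalisation; adjusted p = 0.509 with an estimated correlation). Housekeeping genes had 0 of 14 members past either test and a median of 0.26 (camera adjusted p = 0.0186, 0.267 under quantile normalisation and 0.112 with a replicate block; adjusted p = 0.404 with an estimated correlation). The remaining 14 lists did not pass. Of these, some passed upwards with 1 library left out: inflammatory genes without control 1, other endocrine markers without control 1 or forskolin 1, cell cycle genes without control 2, acinar markers without control 2 or forskolin 1, and neuroendocrine and secretory genes without forskolin 1. Beta cell identity genes passed downwards under quantile normalisation and without forskolin 2. Beta cell identity genes held 1 increase, Irs2, and 1 decrease, Rfx6, among 23. Insulin transcripts did not pass, with Ins1 at -0.19 (adjusted p = 0.803) and Ins2 at -0.17 (adjusted p = 0.778). The inflammatory regulator Tnfaip3 rose by 1.93 and Il1b by 0.76, the cell cycle gene Pcna by 2.10, the synaptotagmin Syt4 by 1.67, and the neuroendocrine list's Cdkn1a by 1.60 and St18 by 1.40.

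Decreases in islets were fewer. Ky fell by 2.65 (SE 0.228, adjusted p = 0.00341), from 8.08 ± 0.19 to 5.43 ± 0.25 (log2 expression, SD, n = 2). The clock genes Dbp and Nr1d1 fell by 1.91 and 1.49, 2 of 18 circadian genes, with 2 up and 4 down when adjusted over the list alone. The endocrine regulator Rfx6 fell by 1.40, the homeobox gene Six4 by 1.41, the innate immune receptor Nod1 by 1.38, Tmem229b by 1.39 and Neurog3 by 0.71. Txnip, an inhibitor of thioredoxin that rises with glucose, fell by 1.39 (SE 0.222, adjusted p = 0.0259). Single libraries decided the number of calls: 123 genes rose and 7 fell without control 1, 114 and 9 without control 2, and 1879 and 961 without forskolin 2, where a lone library is assumed to vary like the other group. Without a control library the calls of Cyp51, Idi1, Insig1, Fbp1, Cebpb, Bag3, Sik2, Cdkn1a, St18, Syt4, Il1b, Nr1d1, Rfx6, Nod1, Neurog3, Tmem229b and Txnip ended. Those of Bag3, Cbarp, Cdkn1a, Cebpb, Il1b, Irs2, Neurog3, Nod1 and Pcna ended without a variance trend, those of Bag3, Cebpb and Neurog3 also with no filter, and those of Insig1 and St18 under quantile normalisation. The camera calls of the cAMP pathway, heat shock and housekeeping lists ended without forskolin 2, the last also without either control.

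**Figure D1:**
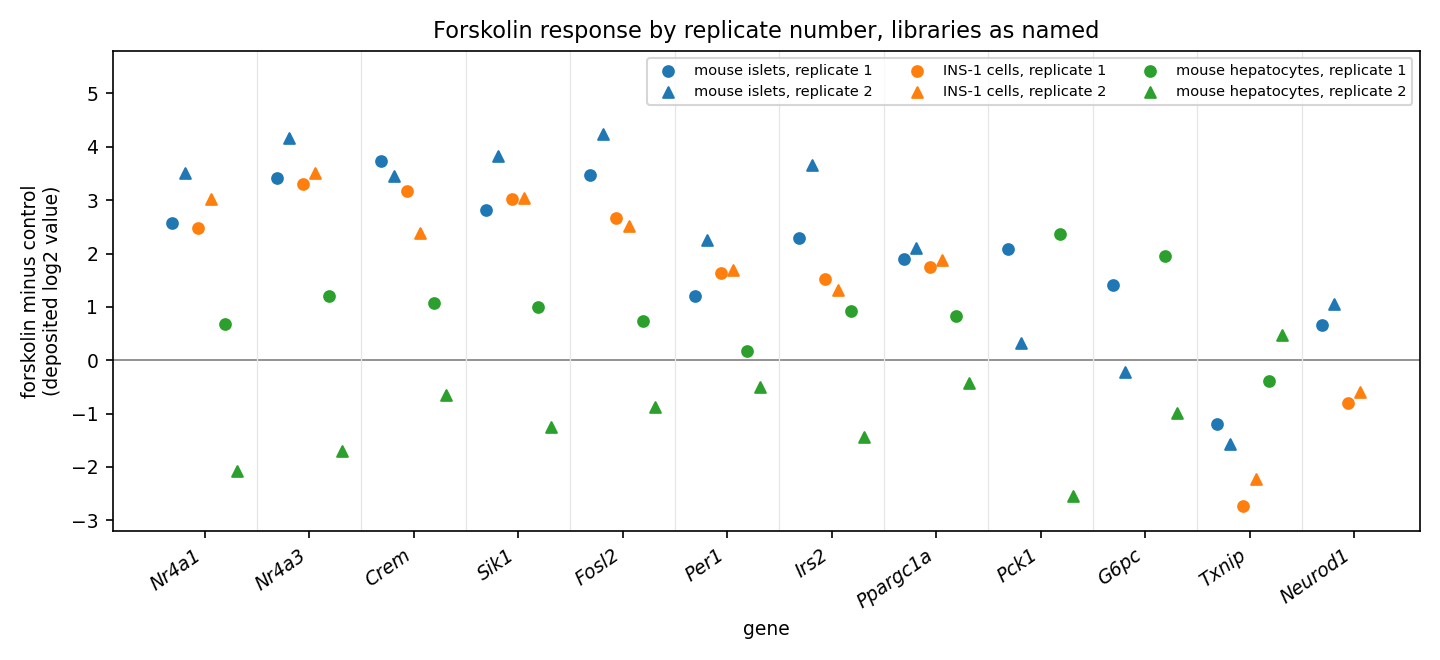
Forskolin minus control difference in deposited log2 expression (vertical axis, log2 units) of 12 genes (horizontal axis), per replicate number and with libraries as named: circles are replicate 1, triangles replicate 2, islets in blue, INS-1 cells in orange and hepatocytes in green. Nr4a3 lies between 3.29 and 4.16 in the islet and INS-1 pairs, while hepatocyte Pck1 lies at 2.36 in replicate 1 and -2.55 in replicate 2.

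In INS-1 cells the same question was asked of a beta cell line without other cell types. Nr4a3 (rn6 chromosome 5, 63781801 to 63821639) rose by 3.40 (SE 0.140, adjusted p = 5.88e-07), a 10.5-fold change from 5.58 ± 0.04 to 8.98 ± 0.18 (log2 expression, SD, n = 2). Sik1 rose by 3.03, Crem by 2.77 and Nr4a1 by 2.75. Txnip had the largest decrease, 10.0 ± 0.38 in controls and 7.56 ± 0.02 with forskolin (log2 expression, SD, n = 2), and fell by 2.48 (SE 0.178, adjusted p = 1.27e-05). Of 10344 genes tested 318 rose and 128 fell, of which 109 and 6 changed by at least 1 on the log2 scale. With a replicate block 774 rose and 691 fell, and without a variance trend 194 and 32.

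Of 24 cAMP and CREB targets 17 rose and none fell, 18 when adjusted over the list alone, with a median of 1.53 (camera adjusted p = 1.47e-33; adjusted p = 0.145 with an estimated correlation). Here Per1 (1.67), Pde4d, the cAMP phosphodiesterase (0.99), and the granule protein Vgf (0.89) were among those that rose, together with Rgs2 (2.44), Ppargc1a (1.82) and Irs2 (1.42). Of 25 immediate-early genes 17 rose and 1, Klf6, fell by 0.65, and 18 rose and 2 fell when adjusted over the list alone (median 1.12, camera adjusted p = 2.08e-22; adjusted p = 0.145 with an estimated correlation). The members that rose included Fosb, Klf4 (2.67), Fosl2 (2.59) and Maff (2.09). Other large increases were in Diras2 (2.89), the activin antagonist Fst (2.58), the VEGF receptor gene Kdr (2.57), the imprinted gene Mest (2.47), the clock repressor Cry2 (2.41), Slc25a25 (2.12) and the cyclin Ccnd1 (1.90).

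Of 23 secretory granule and exocytosis genes 3 rose in INS-1 cells, 5 when adjusted over the list alone (median 0.27, camera adjusted p = 6.38e-05; adjusted p = 0.245 with an estimated correlation): Syt4 (1.20), Vgf and Syt7 (0.69). Of 22 neuroendocrine genes St18 (0.93), Cdkn1a (0.79) and Neurod2 (0.64) rose and Neurod1 fell by 0.69, with 7 up and 2 down when adjusted over the list alone (median 0.29, camera adjusted p = 2.92e-04; adjusted p = 0.324 with an estimated correlation). Both list calls ended under quantile normalisation, with adjusted p of 0.145 and 0.163. Beta cell identity genes split: Irs2 rose while Neurod1 and Rfx6 fell by 0.69 and 0.58 among 19, with 3 up and 4 down when adjusted over the list alone. Ins1 stood at 0.58 (adjusted p = 0.261) and Ins2 at 0.35 (adjusted p = 0.33), neither past the test, although Ins1 passed with a replicate block. The transcription factor Atf4 (0.75) and the pseudokinase Trib3 (0.52) were the 2 of 13 stress response genes that rose, 6 when adjusted over the list alone (median 0.49, camera adjusted p = 4.03e-05; adjusted p = 0.492 with an estimated correlation).

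Slc25a25, Ppargc1a and Cebpb (0.89) were the 3 of 10 gluconeogenesis genes that rose in INS-1 cells, with 4 up and 1 down when adjusted over the list alone (median 0.16, camera adjusted p = 0.00777; adjusted p = 0.324 with an estimated correlation). Of 28 cAMP pathway components 5 rose, 7 when adjusted over the list alone (median 0.12, camera adjusted p = 0.00281; adjusted p = 0.324 with an estimated correlation), namely Sik1, Crem, Rgs2, Pde4d and Sik3 (0.60). Sik3 and the immediate-early gene Klf6 lie outside the naming rule, and their calls were not followed through the other settings. The chaperone Hspa8 (0.56) was the 1 of 8 heat shock genes that rose, also over the list alone (median 0.27, camera adjusted p = 0.0316, 0.141 under quantile normalisation; adjusted p = 0.324 with an estimated correlation). Of 14 cholesterol synthesis genes only Insig1 (1.10) passed over all genes, 2 when adjusted over the list alone. Among 14 circadian genes Cry2 and Per1 rose and Nr1d1 fell by 0.49, with 3 up and 4 down when adjusted over the list alone; the median was -0.13 and the mean 0.16, and camera pointed down without passing. Hexim1, a transcriptional inhibitor known to respond to bromodomain inhibitors, rose by 0.87. Beyond Txnip, decreases were seen in its relative Arrdc4 by 1.12, in the glycogen regulator Ppp1r3b by 1.22, in the RNA-binding protein gene Elavl4 by 1.09, and in Klhl23 by 1.06, Ypel2 by 0.96, Anks4b by 0.87 and Grb7 by 0.84. Calls numbered 197 up and 65 down without control 1, 232 and 61 without control 2, 229 and 36 without forskolin 1, and 366 and 145 without forskolin 2. Without a variance trend the calls of Arrdc4, Atf4, Ccnd1, Cdkn1a, Elavl4, Hspa8, Neurod1, Neurod2, Nr1d1, Rfx6 and Trib3 ended, and under quantile normalisation those of Atf4, Cdkn1a, Hspa8, Neurod2, St18 and Syt7. Leaving out 1 library ended the calls of Atf4, Cdkn1a, Hspa8, Neurod1, Neurod2, Nr1d1, Rfx6, St18, Syt7, Trib3 and Vgf and, for the lists, of heat shock without either control or forskolin 1 and of stress response without control 1 (camera adjusted p = 0.0748). Lists that passed upwards in other settings alone were housekeeping with a replicate block, acinar without control 2, cholesterol synthesis without control 2 or forskolin 1, and inflammatory genes without forskolin 1. Cell cycle and lipogenesis genes passed downwards under quantile normalisation.

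Hepatocytes were compared because gluconeogenic genes are the classical cAMP response of liver. In the authors' deposited table Pck1, the rate-limiting enzyme of gluconeogenesis, had a log2 fold change of 4.16 (adjusted p = 3.67e-79). Tat, a tyrosine-degrading enzyme, had 2.57, Nr4a3 2.33, the chemokine receptor Ackr3 2.03, Nr4a2 1.83 and Slc25a25 1.82 in the authors' deposited table. Further values in the authors' deposited table were 1.76 for the cationic amino acid carrier Slc7a2, 1.68 for the kinase Sgk1, 1.67 for Irs2, 1.56 for the glucose-releasing phosphatase G6pc, 1.53 for Sik1, 1.47 for Egln3, 1.37 for Pde4d, 1.22 for Crem, 1.14 for Nfil3, 1.12 for Socs3, 1.09 for Dusp1, 1.01 for Klf4 and 0.94 for Ppargc1a, each past adjusted p of 0.05. Nr4a1 (0.36) and Per1 (0.45) did not pass in the authors' deposited table, and passed in limma with the replicate 2 columns exchanged and a replicate block. The 7 lower genes in the authors' deposited table included the chemokine Cxcl1 (-1.27), Cyr61 (-0.93), Phlda1 (-0.91), the vasoconstrictor Edn1 (-0.88), Cited2 (-0.82) and Nuak2 (-0.80), against 50 higher genes. By list, the authors' deposited table had 14 of 26 cAMP and CREB targets higher, 7 of 15 gluconeogenesis genes, 5 of 32 cAMP pathway components, 4 of 27 immediate-early genes and 0 of 18 hepatocyte markers.

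The deposited hepatocyte columns did not give this response when read by their names. With limma on the columns as named, 0 of 12593 genes rose and 0 fell, with 32 genes at an unadjusted p under 0.05, 50 and 7 calls in the authors' deposited table, and no gene list past the threshold. Pck1 was 2.36 higher in forskolin 1 than in control 1 and its difference was -2.55 between forskolin 2 and control 2, and cAMP and CREB targets had medians of 0.63 and -0.65 in those pairs. Gluconeogenesis genes had medians of 0.83 and -0.42. Per the file headers, the command that made the table lists the replicate 2 libraries in the other order and gives a forskolin time of 1 h for that library, while the column names and the labels give the reading used here. Across 8985 genes, which are not independent replicates, the authors' deposited fold changes had a correlation of 0.202 with the columns as named and of 0.977 with the replicate 2 columns exchanged. With that exchange, chosen after seeing the data, 3 genes rose and 0 fell, with 383 genes at an unadjusted p under 0.05, and with a replicate block in addition 395 rose and 227 fell. The 3 genes that rose with the exchange alone did so by 2.45 for Pck1 (SE 0.0918, adjusted p = 0.00191), 1.75 for Tat (adjusted p = 0.0273) and 1.24 for Ackr3 (adjusted p = 0.0287). Also with the exchange alone, cAMP and CREB targets had 2 of 23 up, 15 when adjusted over the list alone (median 0.63, camera adjusted p = 9.11e-40; adjusted p = 0.203 with an estimated correlation), and gluconeogenesis genes 2 of 15, 8 over the list alone (median 0.47, camera adjusted p = 1.49e-21; adjusted p = 0.203 with an estimated correlation). Components of the cAMP pathway had 0 of 30 up, 6 over the list alone (median 0.03, camera adjusted p = 7.67e-06; adjusted p = 0.569 with an estimated correlation). As named, 4 genes rose without forskolin 2, and none without any other single library; with the exchange, leaving out 1 library gave 51 and 25 calls without control 1, 58 and 5 without control 2, 36 and 1 without forskolin 1 and 45 and 3 without forskolin 2.

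The induced genes of islets and INS-1 cells overlapped. Of 9168 genes tested in both, 180 were induced in islets and 105 in INS-1 cells, and 50 were shared, against 2.06 for independent lists (one-sided Fisher exact test, p = 3.52e-59). The shared genes included Nr4a1, Nr4a2, Nr4a3, Fos, Fosb, Fosl2, Junb, Egr1, Atf3, Crem, Sik1, Rgs2, Gem, Irs2, Ppargc1a, Slc25a25, Insig1, Klf4, Btg1, Btg2, Mest, Syt4 and the gut and islet peptide gene Cck. Txnip was the 1 gene that fell by at least 1 on the log2 scale in both, of 19 and 5 (one-sided Fisher exact test, p = 0.0103). Hepatocytes shared 0 genes with either as their columns are named, since no gene was called. From the authors' deposited tables, 14 genes were induced in both islets and hepatocytes against 0.861 for independent lists (one-sided Fisher exact test, p = 1.49e-14) and 12 in both INS-1 cells and hepatocytes against 0.584 (one-sided Fisher exact test, p = 6.86e-14). Crem, Dusp1, Irs2, Klf4, Nfil3, Nr4a2, Nr4a3, Pde4d, Sik1 and Slc25a25 stood in both of those sets from the authors' deposited tables. Whether any response differed in size between the cell types was not tested.

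CRTC2 is a coactivator that binds CREB when cAMP rises, and islets of knockout mice were given forskolin to ask how far the response needs it. There were no replicates in this and the following comparisons, so differences are those between single libraries and carry no test. Crtc2 itself was lower but present: 18.7 FPKM in wild-type control, 7.77 in knockout control, 13.9 in wild-type forskolin and 9.58 in knockout forskolin, and whether the deleted part lies among the counted exons is not given in the sources used here. CREB targets were higher with forskolin in the knockout too. Fos went from 2.25 to 170 FPKM there and from 5.09 to 329 in wild-type, Sik1 from 1.76 to 85.9 and from 2.40 to 127, Dusp1 from 5.19 to 211 and from 7.57 to 288, and Irs2 from 6.13 to 138 and from 8.39 to 267. Nr4a1 went from 7.09 to 82.5 FPKM in the knockout and from 3.26 to 159 in wild-type, Nr4a3 from 0.20 to 32.3 and from 0.52 to 93.4, Gem from 1.99 to 46.0 and from 0.64 (3 estimated reads) to 107, and Crem from 8.87 to 153 and from 11.7 to 313.

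As a group, the 99 measured genes induced in INS-1 cells had a median log2 response of 1.89 in wild-type and 1.52 in knockout islets. The median difference per gene was -0.38 (bootstrap over genes -0.48 to -0.23), below all 10000 matched random lists. Those lists were matched on expression and not on forskolin response. The rank therefore cannot tell a knockout effect from any other difference in response size between the 2 pairs of libraries. For 26 cAMP and CREB targets the medians were 3.47 and 3.21, and the difference of -0.31 had an interval of -0.61 to 0.03. Gem (-2.06), Nr4a1 (-1.86), Rgs2 (-1.76), Fosb (-1.22) and Nr4a3 (-1.15) had the larger negative differences among them, while Sik1 (-0.25), Per1 (0.07) and Dusp1 (0.02) lay near 0. Part of the differences of Nr4a1, Gem and Rgs2 lay in the controls, where knockout over wild-type log2 ratios were 0.93, 0.87 and 0.48, against -0.94, -1.20 and -1.29 with forskolin. The 26 immediate-early genes had medians of 3.35 and 2.69 and a median difference of -0.06. For 215 genes induced in wild-type islets the difference was -0.49, but that list was chosen partly on these libraries: the forskolin ratios of the wild-type columns here had a correlation across 4772 genes of 0.985 with islet replicate 2. The 26 genes induced in hepatocytes by the authors' deposited table had medians of 1.30 and 1.87 and a difference of -0.07 (interval -0.52 to 0.37). Cholesterol synthesis genes had medians of 1.32 and 1.45, and stress response genes 0.97 and 0.93.

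Markers of other cell types differed between the genotypes in both treatments. The median of 18 hepatocyte markers was 2.87 higher in knockout than wild-type controls and 4.83 higher with forskolin, with Alb at 41.2, 298, 45.2 and 1436 FPKM in wild-type control, knockout control, wild-type forskolin and knockout forskolin, and Apoa1 at 3.50, 95.9, 6.88 and 434. Pck1 followed the same order, 1.44, 11.7, 3.20 and 47.5 FPKM. Acinar markers went the other way, with a median knockout to wild-type log2 ratio of -3.18 in controls and -2.01 with forskolin. The digestive protease Ctrb1 stood at 1826 FPKM in wild-type and 138 in knockout control. The knockout forskolin library had the lowest estimated depth, 0.60 M reads.

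**Figure D2:**
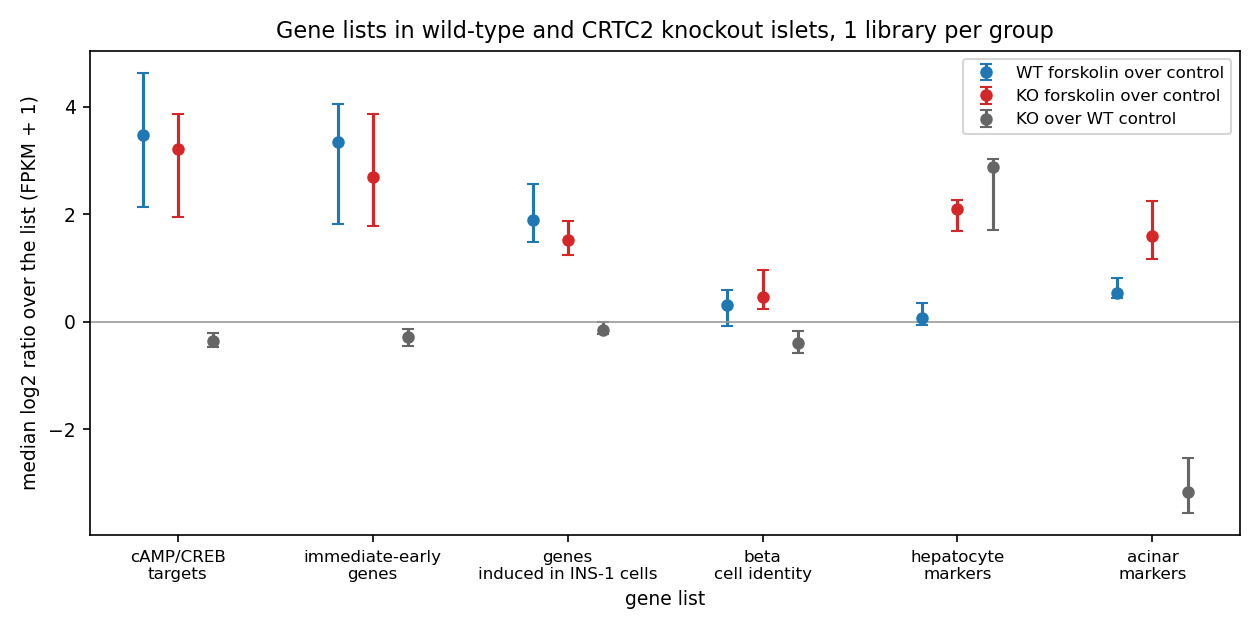
Median log2 FPKM ratio (pseudocount 1) of 6 gene lists in the knockout table, for forskolin over control in wild-type and in CRTC2 knockout islets and for knockout over wild-type controls; bars are bootstrap intervals over genes, with 1 library per group. The cAMP and CREB targets lie at 3.47 and 3.21 in the 2 genotypes, and hepatocyte markers lie at 2.87 in knockout over wild-type controls.

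JQ1 blocks the acetyl-lysine pocket of BET bromodomain proteins, and A-485 inhibits the acetyltransferase activity of p300 and CBP, coactivators that bind CREB. They are structurally unrelated and were used at different doses, 1 and 10 µM, each for 4 h, in INS-1 cells given forskolin for 2 h. More of the response was missing with A-485 than with JQ1. Of 105 genes induced in the replicated INS-1 comparison, under 50% of the log2 induction was kept for 73 genes with A-485 and for 20 with JQ1, and the median share kept was 29.1% and 89.8%. Of 20 cAMP and CREB targets induced by at least 1 on the log2 scale here, 10 with A-485 and 3 with JQ1 kept under 50%. Their median share kept was 50.5% and 93.1%. The 105 induced genes had a median log2 response of 2.90 to forskolin alone. Against forskolin alone, their median was -0.36 for JQ1 with forskolin (bootstrap over genes -0.53 to -0.11) and -1.93 for A-485 (-2.29 to -1.73). Crem stood at 12.1 FPKM in control, 421 with forskolin, 336 with JQ1 added and 76.5 with A-485 added. In the same order Nr4a3 stood at 1.15, 114, 61.4 and 14.6 FPKM, Sik1 at 4.67, 244, 183 and 63.8, and Irs2 at 48.7, 278, 289 and 65.5.

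Some targets were low with both inhibitors and others with neither. Ppargc1a stood at 37.6 FPKM with forskolin, 5.42 with JQ1 and 1.64 with A-485, Ccnd1 at 33.3, 2.25 and 0.70, Fst at 142, 5.01 and 1.95, and Pde4d at 38.7, 10.3 and 8.94. Nr4a1 went the other way, at 371 FPKM with forskolin, 616 with JQ1 and 692 with A-485, as did Junb at 520, 914 and 1638 and Egr1 at 74.9, 218 and 160. The 23 cAMP and CREB targets had medians of -0.10 for JQ1 and -1.63 for A-485 against forskolin alone, and 25 immediate-early genes had 0.43 and -0.55. Vgf stood at 1154, 6349 and 1523 FPKM. Of the 105 genes 27 were lower by at least 1 on the log2 scale with JQ1 and 6 higher, and with A-485 81 were lower and 2 higher.

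**Figure D3:**
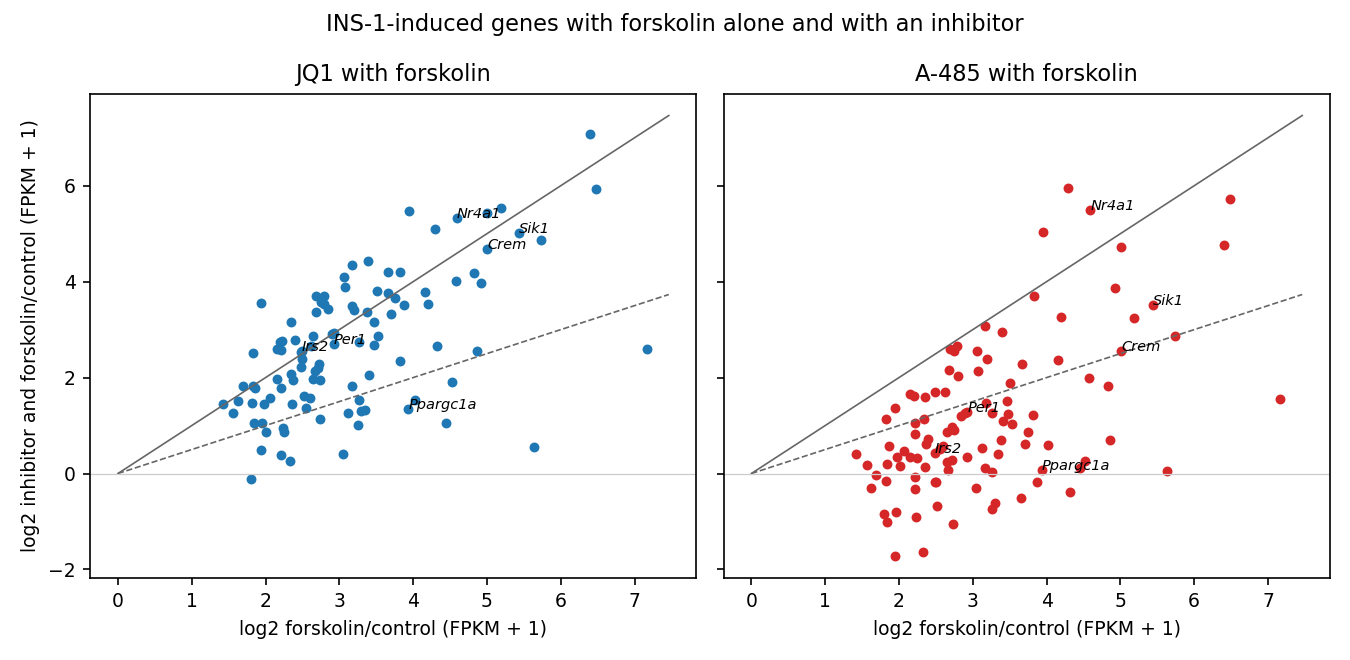
Log2 FPKM ratio to control (pseudocount 1) of 105 genes induced in the replicated INS-1 comparison, with forskolin alone (horizontal axis) and with JQ1 or A-485 added (vertical axes of the 2 panels); each point is a gene, the solid line marks equal ratios and the dashed line 50% of the log2 induction. With A-485 73 genes lie under the dashed line, and with JQ1 20.

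Beta cell identity genes were also lower with A-485, with a median of -2.03 over 20 members against forskolin alone and -0.16 with JQ1. Neurod1 stood at 137 FPKM in control, 44.5 with forskolin, 83.1 with JQ1 and 4.63 with A-485. In the same order the pancreatic regulators Nkx2-2 stood at 51.2, 90.0, 11.8 and 2.90 and Foxa2 at 73.5, 150, 77.6 and 8.45. The potassium channel gene Kcnj11 stood at 125, 99.6, 20.05 and 4.15 FPKM in that order. Neuroendocrine genes had medians of -0.07 with JQ1 and -1.16 with A-485, and secretory genes -0.13 and -0.77. Ins1 had log2 ratios to forskolin alone of 0.02 with JQ1 and -0.77 with A-485. Hexim1, which rises with BET inhibitors in many cell types, stood at 32.3, 96.5, 555 and 318 FPKM, and Myc at 68.9, 69.4, 27.2 and 3.83. The induced list may overlap these libraries: across 5690 genes the forskolin ratios here had a correlation of 0.925 with INS-1 replicate 1 and 0.753 with replicate 2, against 0.766 between the replicates. No inhibitor was given without forskolin in the samples used here, so effects on baseline and on induction were not separated.

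The AR42J comparison asked whether NeuroD1, a transcription factor of endocrine and neural cells, alters the forskolin response of an exocrine line. Neurod1 stood at 3.44 and 5.67 FPKM in GFP control and GFP forskolin cells and at 3323 and 3834 in NeuroD1 control and NeuroD1 forskolin cells. With the pseudocount of 1 FPKM, which understates changes of low genes, 25 cAMP and CREB targets had median forskolin responses of 0.73 with GFP and 0.96 with NeuroD1. The median difference per gene was 0.18 (bootstrap over genes 0.03 to 0.31), at percentile 98.6 of random lists, which were not matched on forskolin response. The 94 genes induced in INS-1 cells had medians of 0.16 and 0.28, with a difference of 0.08. Crem stood at 1.97, 5.93, 5.48 and 17.2 FPKM in GFP control, GFP forskolin, NeuroD1 control and NeuroD1 forskolin cells, Nr4a1 at 1.15, 3.76, 3.09 and 15.8, Irs2 at 34.7, 112, 31.0 and 117, and Pck1 at 1.41, 10.9, 1.26 and 6.32.

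In AR42J cells Cyp1a1 had forskolin log2 ratios of 6.63 with GFP and 6.49 with NeuroD1, Cyp1b1 3.70 and 3.85, both known targets of the aryl hydrocarbon receptor, and the natriuretic peptide gene Nppc 3.21 and 3.47. Txnip had -2.21 and -2.03. Gluconeogenesis genes had medians of 0.37 and 0.31 and immediate-early genes -0.02 and 0.18. Relative to GFP controls, medians were 0.65 for 19 neuroendocrine genes, 0.70 for 12 beta cell identity genes, 0.69 for 23 secretory genes, -0.94 for 20 acinar markers and -1.18 for 16 cell cycle genes. The neuroendocrine and beta cell identity lists include Neurod1 itself, the added gene. The gut hormone gene Sct stood at 23.3 FPKM in GFP and 644 in NeuroD1 controls, Rfx6 at 0.73 and 14.4, Scg2 at 4.30 and 30.7, Rgs2 at 3.85 and 52.1, and Cplx2 at 18.6 and 99.4, while Pax4 and Pcsk1 were listed at 0 in GFP controls and stood at 30.4 and 10.4. The carboxypeptidase Cpa1 stood at 8003 and 3378 FPKM, the lipase Pnlip at 2426 and 708, and the proliferation marker Mki67 at 76.5 and 28.6. Ribosomal protein genes were not read as changed, since near-identical copies share their reads.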

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

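The tests of exchanged names, of an absent response, of forskolin raising hepatocyte genes, of dilution, of islet preparations and of the loss of CRTC2 were chosen after the result was seen; the counts of hepatocyte transcripts and the test of depth were set before it.

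Of the genes named for islets or INS-1 cells, 2 moved one way in every pair of libraries of 1 cell type and the opposite way in every pair of another. These differences were not tested. Genes named only for other comparisons were not screened. Hepatocyte columns were read as named, where replicate 2 ran against replicate 1, so the screen says little about hepatocytes. In the authors' deposited tables Phlda1 stood at 2.87 in islets and -0.91 in hepatocytes. Arrdc4 differed by 0.70 in islets and by -1.12 in INS-1 cells on the log2 scale, and Neurod1 by 0.86 and -0.69. Opposite directions in all libraries were seen for 577 of 9168 genes, 6.29%, between islets and INS-1 cells.

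The replicate 2 hepatocyte libraries went against their names. In them the cAMP and CREB targets had a median difference of -0.645 between the library named forskolin and the one named control, under the lowest of 10000 random matched lists at -0.075, which argues against an absent response in that pair, since such a median would lie among the random lists. An exchange of the column names in that pair is a candidate explanation that the same value, the order of libraries in the command per the file headers and the authors' deposited fold changes are consistent with. The authors' fold changes and the header are not independent of each other, and an exchange of the libraries before the table was made was not tested. No biological explanation was tested, because the design gives none for a reversal in 1 pair.

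Hepatocyte transcripts were high in islet forskolin 1 and in both knockout libraries. A response of these genes to forskolin is argued against for islets by replicate 2, where the median difference of the hepatocyte markers was 0.027. RNA from hepatocytes may be a source but is undecided. Of the 50 most abundant hepatocyte transcripts scarce in islet controls, 30 were at least 2-fold above every other islet library in forskolin 1. In both knockout libraries 27 were so against the wild-type columns. Both counts lay between the bounds set before, 45 for such RNA and 25 against it. The 50 were picked by abundance in these cultured hepatocytes and include Saa3, at 0 CPM in every wild-type islet library. The counts thus bear on that profile alone. The regularised scale also shrinks folds of low genes, which makes the bound of 45 harder to reach in forskolin 1. The transcripts did not rise in 1 ratio: Alb stood at 7852 CPM in hepatocytes, 183 in islet control 1 and 1597 in islet forskolin 1, while the more abundant Hpx stood at 14373, 8.56 and 52.6, Cp at 8049, 6.01 and 17.6, and Clu, the most abundant of the 50 and also expressed by islets, at 24568, 250.0 and 272. These levels go against RNA with the profile of the cultured hepatocytes used here, another liver profile was not tested, and the knockout genotype stays open as untested for its 2 libraries.

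The INS-1-induced genes had a smaller forskolin response in knockout islets. Dilution by RNA of other cells stays open. The beta cell identity genes had a knockout minus wild-type response of 0.323, where dilution growing from knockout control to knockout forskolin would lower it. A share of other RNA alike in both knockout libraries would cancel in that value, so it cannot decide. Low depth of the knockout forskolin library stays open. The 85 genes with at least 20 estimated reads in the control or forskolin library of each genotype had -0.346 (bootstrap over genes -0.453 to -0.193). Those reads could lie in the deeper knockout control, so the filter did not require depth in the knockout forskolin library and cannot decide. A difference between islet preparations may contribute and stays open: the response of the same genes differed by -0.282 (quartiles over genes -0.743 and 0.027) between wild-type replicates 1 and 2 on the regularised scale, which shrinks differences, and the wild-type columns of the knockout table resemble replicate 2, the one with the larger response. Loss of CRTC2, with a median of -0.38, cannot be told apart from a preparation difference, low depth or dilution with 1 library per group.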

How the results depend on the processing

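The block, leave-out, filter, threshold, estimated-correlation and pseudocount settings were planned; the exchanged columns with their block and leave-out settings, the authors' deposited comparison, the group mean of 5, quantile normalisation, the model without a variance trend and the crossed block were chosen after seeing the data, and unless a construction is named the cause of a change was not tested. Deviations of same-numbered libraries had correlations across genes of -0.129 in islets, 0.411 in hepatocytes and 0.459 in INS-1 cells. Hepatocyte libraries had correlations across genes of 0.995 within number 1 and 0.997 within number 2. Those between the 2 controls and between the 2 forskolin libraries were 0.99 and 0.988. The hepatocyte libraries thus lay closer by number than by treatment, and their depth also split by number. Whether they were paired by design is not given by the labels. A pairing by number is not established by the labels in the other cells either, was not seen in islets and stays open in INS-1 cells. With a replicate block calls were 667 up and 120 down in islets, keeping all 235 and 33, and 774 and 691 in INS-1 cells, and with a crossed block 542 and 163 in islets; 1 list rose in hepatocytes with the block. In the authors' deposited table calls were 483 and 63 in islets, sharing 234 and 31, and 50 and 7 in hepatocytes. Islet decreases numbered 18 with no filter (more genes tested), 56 at a group mean of 5 (fewer genes tested) and 12 without a variance trend; INS-1 calls were 194 and 32 without the trend and 109 and 6 with a log2 change of at least 1. With the hepatocyte replicate 2 columns exchanged 3 genes and 3 lists rose, and with a replicate block in addition 395 genes rose, 227 fell and 4 lists rose. Leaving out 1 library, where a lone library is assumed to vary like the other group, gave 114 to 1879 increases and 7 to 961 decreases in islets, 197 to 366 and 36 to 145 in INS-1 cells, 0 to 4 increases and 0 to 6 raised lists in hepatocytes as named, and 36 to 58 increases and 1 to 25 decreases with exchanged columns. Shared induced genes of islets and INS-1 cells numbered 84 with no minimum fold and 111 in the authors' deposited tables; for islets and hepatocytes they numbered 1 with exchanged columns, 8 with the block in addition and 14 in the authors' deposited tables, and for INS-1 cells and hepatocytes 1, 7 and 12. With an estimated correlation 0 lists rose in islets and 0 in INS-1 cells. That setting also missed the list planted in simulated data for both designs, where genes varied independently of each other. Under quantile normalisation 5 lists rose in INS-1 cells. The hepatocyte marker median in islets ran from -0.31 without forskolin 1 to 3.08 without forskolin 2. In knockout islets the INS-1-induced genes had a median response of 1.23 with a pseudocount of 5, and the islet-induced genes 2.34 with 0.25 and 1.54 with 5; with 5 the INS-1-induced genes had 2.51 with forskolin in the inhibitor table and 0.17 in NeuroD1 cells, and the cAMP and CREB targets 0.31 in GFP cells, since a larger pseudocount shrinks low genes. Summary values stayed within 1.5 times or their spread in 205 cases and moved further in 64. List results kept their side of the threshold in 384 cases, which include lists called in neither setting. They gained a call in 50, lost it in 32 and reversed in 1. Named genes kept their side of the threshold in 427 islet, 406 INS-1 and 288 hepatocyte settings, lost it in 43 and 41, and gained it in 11, 1 and 60. Other size factors, a count-based tool of its own, pseudocounts for the log2 tables, other transcripts and the test of islets against hepatocytes were not run, because they need counts, another scale or a joint table. Depth is 1 limit of the knockout comparison, with 0.60 M estimated reads in 1 library.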

Other observations

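No tests are reported in these paragraphs, so none was chosen after the result was seen. The genes follow the naming rule set before the data were examined. Each FPKM value comes from 1 library, and the list medians are of ratios between single libraries.

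Further genes differed with the inhibitors in INS-1 cells. Several were higher with JQ1 and forskolin than with forskolin alone: Cited4 stood at 1.62 FPKM with forskolin, 37.0 with JQ1 and 12.6 with A-485, the ETS factor gene Etv5 at 2.21, 39.8 and 25.4, Fgf18 at 1.82, 43.6 and 9.06, and the netrin receptor gene Unc5b at 4.32, 54.2 and 18.9. In that gene order the controls stood at 4.48, 4.83, 7.21 and 2.42 FPKM. The forskolin library held 6, 34, 4 and 48 estimated reads of them, and the genes were chosen on ratios to that library. Klf2 stood at 25.7, 169 and 163 FPKM, and the opioid precursor gene Penk at 9.19, 42.7 and 67.0. The relaxin family receptor gene Rxfp3 and the lipase inhibitor gene G0s2 were low with both, Rxfp3 at 84.8, 1.53 and 0.80 FPKM and G0s2 at 144, 2.58 and 0.30. Txnip stood at 160 FPKM in control, 12.9 with forskolin, 57.5 with JQ1 and 58.5 with A-485. Cell cycle genes had a median log2 ratio to forskolin alone of -0.34 with JQ1 and 0.16 with A-485.

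In AR42J cells the defensin genes Defa24 and Defa8 stood at 96.4 and 0 FPKM in GFP controls and at 4329 and 82.0 in NeuroD1 controls, and such gene families share near-identical copies. Caly stood at 0.34 and 89.7 FPKM, Hepacam2 at 1.64 and 172, Rab3b at 0.28 and 59.8, and Gdf15 at 127 and 15.6. Heat shock genes had median forskolin log2 ratios of -0.22 with GFP and 0.22 with NeuroD1.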
